A study of Homo sapiens with 56 samples.

How the data were processed

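RNA sequencing of T-HESC cells after siRNA knockdown of 7 transcription factors was used as the authors deposited it, as 1 table of results per knockdown. Per the labels, cells were transfected with 50 nM siRNA for 6 h and harvested at 48 h, and single-end reads of 50 bp were sequenced. The labels state that knockdown was checked by quantitative PCR with over 70% reduction. The 56 GEO samples are 28 libraries with runs a and b each, taken here as 2 runs of 1 library because they share a library label. The labels assign 3 control libraries to each knockdown. They describe the replicates as biological; the p-values measure the spread between these libraries.

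Per the submitters' processing notes, HISAT2 2.1.0, StringTie 1.3.6, edgeR, limma and DESeq2 2.11.40.6 were used with the hg38 assembly. The notes give no role or parameter for each tool. The method that assigned reads to transcripts and the release of the annotation are not given in the sources used here. The deposited signal values are means, over the libraries of a comparison, of read counts divided by size factors that the authors computed per table, so tables were normalised separately. The deposited log2 values are fold changes of knockdown over control and their standard errors, both from the authors' fit; the direction was read from the targeted genes. The deposited score is the authors' Wald statistic, the fold change divided by its standard error, and no line departed from that ratio. The authors' p-value columns hold a Wald p-value and an adjusted p-value, missing where the authors' filter removed a transcript.

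The files held transcripts rather than the genes that the plan had assumed. Each table listed the same 100454 transcript identifiers. Matching without version numbers to GENCODE 29 on GRCh38, the reference used here for gene symbols and coordinates, named 83066 of them (82.7%) and between 94.4% and 94.7% of those with an adjusted p. Between 18914 and 20247 transcripts per table had an adjusted p. No table holds values of single libraries. The lowest means in each table were whole multiples of what 1 read in 1 library is worth. From these, 6 single-read values per table were found, 3 in control and 3 in knockdown libraries, which is what 3 libraries per arm give, whether runs a and b had been summed or a single run was used. The size factors derived from them ran from 0.815 to 1.15. Mean normalised totals lay between 5225514 and 5687356 per library. At that depth the authors' standard error of one-transcript loci with a mean of at least 100 had a median of between 0.20 and 0.27 per table on the log2 scale, while POU6F1, with a mean of 17.6, had 0.58.

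Arm means were solved from each mean and fold change for 3 libraries per arm. Transcripts of genes whose exons overlap on the same strand were joined to loci, and locus sums were compared with a pseudocount of 0.5. A transcript with at least 90% of its locus in both arms was treated as a one-transcript locus, a division added after the values were seen. Calls used the authors' adjusted p under 0.05. A list member was represented by its most abundant transcript.

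Comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 7 targets in every table. It takes up to 6 called genes with the largest rise and 6 with the largest fall at a mean of at least 100. It takes up to 4 called members per list with at least 2 called members or a passing test. It takes up to 10 genes called in the same direction in the most tables. Because most of the largest values were transcripts of shared loci, the second and last parts were applied to one-transcript loci after the values were seen. Genes named beside a count adjusted over the list alone, single called members of lists that did not pass, and relatives of the targets lie outside the rule and were chosen after their values were seen.

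The 23 gene lists covered decidualization, stromal fibroblast identity, G1/S, mitosis, histones, immediate-early genes, SRF and MRTF targets, TGF-beta response, extracellular matrix, interferon-stimulated genes, NF-kB targets, p53 targets, telomere genes, amino acid and unfolded protein response, cholesterol biosynthesis, hypoxia, ribosomal proteins, mitochondrially encoded genes, autophagy and markers of 4 other cell types. Lists with at least 3 measured members were tested on the deposited Wald statistics of genes with a mean of at least 10 by limma cameraPR, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 147 tests. Members were also adjusted over the list alone, and list medians were ranked among 10000 random lists matched on expression in 20 bins. The cholesterol list in TERF1, for example, lay at percentile 0.01. An estimated correlation needs values of single libraries, so a preset of 0.05 was the alternative.

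Words of 7 bases in the 3' UTRs of GENCODE 29 were tested in one-transcript loci with a mean of at least 100. The log2 fold change, limited to 3 in absolute value, was regressed on the presence of each word found in at least 20 UTRs, with UTR length, base composition and expression as covariates. Bonferroni correction covered 114688 tests. The share of genes with the leading word is given as a description. The siRNA sequences were not used here.

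Relations between the 21 pairs of knockdowns used Pearson correlation and covariance across transcripts with a mean of at least 100 in both tables. Each was set beside 100 simulations without effects, in which chance values with the deposited standard errors were drawn and shared through the control libraries in common. Counts of transcripts called in several tables were set beside the same simulation and beside independent lists.

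The steps were tested on simulated data. This used one-transcript loci with a mean of at least 100, between 4130 and 4402 per table. Among them, 100 changes of 1 and 100 of 2 on the log2 scale were planted per table with the deposited standard errors. Between 67 and 83 of the smaller and between 93 and 98 of the larger changes were called, all in the planted direction, and between 6 and 15 unchanged transcripts. Benjamini-Hochberg adjustment covered these loci alone, and chance values were drawn from the same standard errors that entered the test. The rates are therefore not those of the authors' calls or of transcripts with lower means. Of 147 list tests, 7 of 7 shifted lists and 1 of 140 others were called. The values of these list tests were drawn independently for each gene, so the check does not cover false calls from correlated genes. Arm means were recovered for 4984 of 4984 transcripts, and in a scan of 4043 UTRs a planted word ranked first, while 0 of 16384 words passed with shuffled fold changes.

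Alternatives were an adjusted p of 0.01, a minimum fold change, other adjustments, an empirical null, standard errors multiplied by the square root of 2, other minimum means, ranks, a preset correlation of 0.05 and Spearman correlation. One-transcript loci, lists without the targeted gene and UTRs without an associated word were added later. Reads were not realigned, and tests between libraries, models with covariates and splits of the control libraries were left out because no values of single libraries were used. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.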

Results

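RNA was sequenced from T-HESC cells, a line of human endometrial stromal fibroblasts immortalised with telomerase, after knockdown of a single transcription factor with a small interfering RNA (siRNA). Endometrial stromal fibroblasts are the cells that turn into decidual cells during pregnancy. The series title sets the knockdowns in a study of gene expression gained in the evolution of pregnancy and decidualization. The 7 targets were E2F3, ELK4, POU6F1, TCFL5, TERF1, TGIF2 and THAP5. Cells received siRNA at 50 nM for 6 h, or a fluorescent non-targeting oligonucleotide as control, and RNA was taken at 48 h. The labels describe 3 biological replicates per knockdown, and the p-values measure the spread between these libraries. The 56 GEO samples are 2 runs each of 28 libraries, of which 21 were knockdowns and 7 were controls in 3 control groups named Ctrl5, Ctrl6 and Ctrl7. Each knockdown was set against 3 control libraries. E2F3 and ELK4 used the 3 libraries of Ctrl5, while TERF1, TGIF2 and THAP5 used the 3 libraries of Ctrl6. POU6F1 used 2 libraries of Ctrl5 and TCFL5 used 2 of Ctrl6, each with the single Ctrl7 library.

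The authors deposited 1 table per knockdown with a mean normalised count, a log2 fold change, its standard error (SE) and p-values for each of 100454 transcripts. Between 27735 and 28508 transcripts per table had reads. The mean normalised counts summed to between 5225514 and 5687356 per library, and the abundant 7SL RNA took between 14% and 24.3% of that sum. Values of single libraries were not used here, so all fold changes, SEs and adjusted p-values below are those of the authors' deposited table of the knockdown named, and positive values mean higher in the knockdown. Transcripts with an adjusted p under 0.05 are described as called.

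Each siRNA target was lower in its own knockdown. The direction of the fold changes was read from these genes, so their sign is not an independent check. In the authors' deposited tables, E2F3 fell by 2.14 on the log2 scale (SE 0.23, adjusted p = 1.26e-17), which left 22.7% of the control level. ELK4 fell by 2.88 (SE 0.23, adjusted p = 5.7e-33, 13.6% left), and THAP5 fell by 2.51 (SE 0.28, adjusted p = 2.39e-16, 17.6% left) in the authors' deposited tables. The authors' deposited tables gave a fall of TERF1 to 8.62% of control (log2 fold change -3.54, SE 0.52, adjusted p = 4.71e-09) and of TGIF2 to 16.4% (-2.61, SE 0.47, adjusted p = 4.97e-06). TCFL5 fell to 20% (-2.32, SE 0.43, adjusted p = 1.14e-05) in the authors' deposited table. POU6F1, with an authors' mean of only 17.6 normalised counts, had a log2 fold change of -1.93 (SE 0.58) and was not called (p = 0.000981, adjusted p = 0.0886) in the authors' deposited table. Its value left 26.3% of control. The same 7 genes were the background for each other: none of their 42 values in the other tables was called, 5 had an unadjusted p under 0.05, and they ranged from -0.94 to 0.56.

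On the GRCh38 assembly, the measured transcripts of the targets spanned bases 20402167 to 20493715 of chromosome 6 for E2F3 (plus strand), and 205607943 to 205631962 of chromosome 1 for ELK4 (minus strand). POU6F1 lay on chromosome 12 from 51189200 to 51217671 (minus strand), and TERF1 on chromosome 8 from 73008864 to 73046471 (plus strand). TCFL5 and TGIF2 both lay on chromosome 20, TCFL5 from 62841115 to 62861763 (minus strand) and TGIF2 from 36573488 to 36593950 (plus strand). THAP5 lay on chromosome 7 from 108562227 to 108569723 (minus strand).

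**Figure D1:**
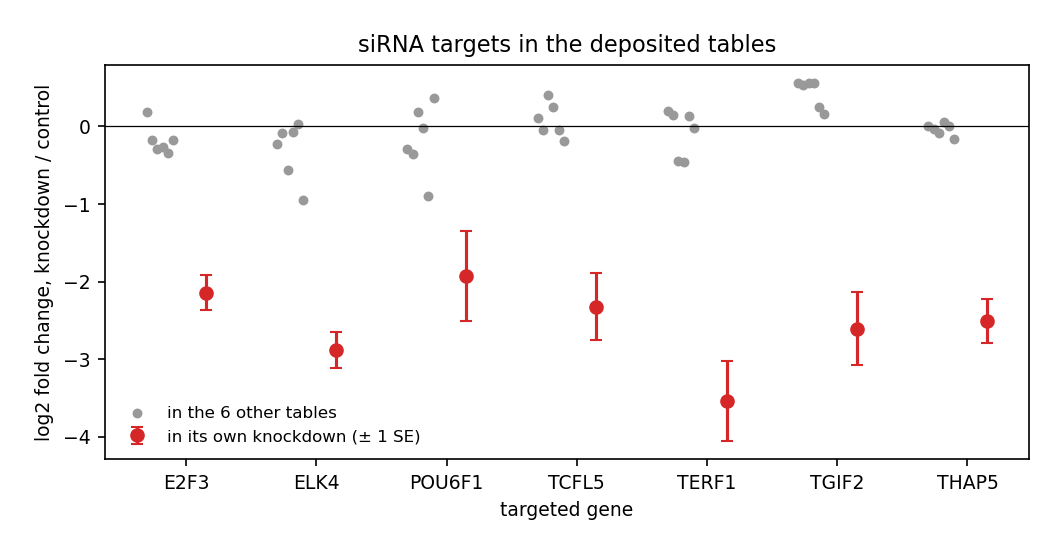
Log2 fold change (knockdown over control, y axis) of each targeted gene (x axis) in the deposited tables, in its own knockdown (red, with 1 SE) and in the 6 other tables (grey). The own values run from -3.54 for TERF1 to -1.93 for POU6F1, and the other 42 values from -0.94 to 0.56.

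Between 183 and 656 transcripts were called per knockdown. E2F3 had 283 (144 rose, 139 fell), ELK4 242 (113 and 129), POU6F1 183 (78 and 105), TCFL5 434 (178 and 256), TERF1 204 (95 and 109), TGIF2 656 (342 and 314) and THAP5 308 (110 and 198). Most of the largest fold changes belonged to transcripts that shared their locus with other measured transcripts. The median absolute log2 fold change of such calls was between 4.92 and 6.35 per table, while the normalised counts summed over their locus changed by a median of 0.16 to 0.37. For example, different TPD52L2 transcripts were listed at 11.21 and -10.91 in the authors' deposited table for E2F3, and the sum over that locus had a log2 ratio of -0.14. Over all tables, the locus sum stayed within 1.5-fold for 79.5% of these calls. Such fitted values come from transcripts listed near 0 in an arm and are no bound on a fold change.

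The accounts below therefore lead with transcripts that held at least 90% of the normalised counts of their locus in both arms, a choice made after the values were seen. These one-transcript calls numbered 132 for E2F3 (68 rose, 64 fell), 81 for ELK4 (35 and 46), 56 for POU6F1 (21 and 35) and 256 for TCFL5 (94 and 162). There were 42 for TERF1 (13 and 29), 402 for TGIF2 (202 and 200) and 129 for THAP5 (26 and 103). Their median absolute log2 fold change was between 0.70 and 1.11.

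**Figure D2:**
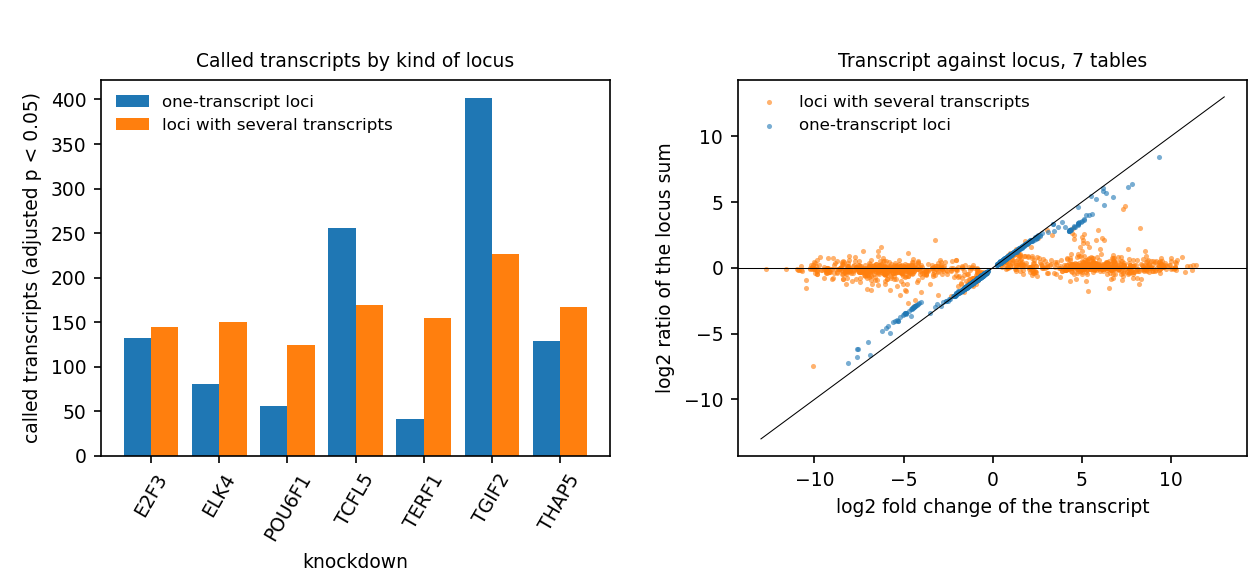
Left, number of called transcripts (y axis, adjusted p under 0.05) per knockdown (x axis) in one-transcript loci (blue) and in loci with several measured transcripts (orange). Right, log2 ratio of the locus sum (y axis) against the log2 fold change of each called transcript (x axis) over the 7 tables, with the diagonal drawn. One-transcript calls, such as 402 for TGIF2, lie along the diagonal, whereas 79.5% of the calls in loci with several transcripts have a locus sum within 1.5-fold of control.

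Short words in the 3' UTRs were tied to lower expression in all 7 tables. For each knockdown, every word of 7 bases was tested for a relation to the log2 fold change of one-transcript loci, with UTR length, GC content and expression in the model. The words most strongly tied to lower expression were GATGCTT for E2F3, ACTGCTT for ELK4, ATCCCAA for POU6F1, GCCTAGA for TCFL5, GTTTCAA for TERF1, GGAAGGA for TGIF2 and CTTGCTA for THAP5. All 7 passed Bonferroni correction over 114688 tests, with the weakest at a Bonferroni adjusted p of 3.31e-07 for POU6F1, and no word passed it for a rise. Transcripts with the word had log2 fold changes lower by between 0.08 for POU6F1 and 0.27 for TCFL5 than those without. Each leading word also occurs in the coding sequence of the targeted transcript. In genome coordinates the 7 bases run upward from 20490377 of chromosome 6 in E2F3, 205620301 of chromosome 1 in ELK4 and 51192372 of chromosome 12 in POU6F1. The others run upward from 62859464 of chromosome 20 in TCFL5, 73039166 of chromosome 8 in TERF1, 36590962 of chromosome 20 in TGIF2 and 108564679 of chromosome 7 in THAP5.

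Among one-transcript loci with a mean of at least 100 normalised counts, 65.2% of the 46 that fell with E2F3 knockdown held its word, against 14.8% of 4176 that were not called. For ELK4 the shares were 69.4% of 36 against 19.6%, for TERF1 75% of 20 against 17.9%, and for TGIF2 62.1% of 116 against 20.9%. Those for THAP5 were 45.0% of 60 against 11.4%, for TCFL5 39.6% of 96 against 7.76%, and for POU6F1 30.4% of 23 against 12.1%. Genes that rose held the word at between 0% and 15.9%. These shares are descriptions, since each word had been picked on the fold changes of the same loci. Some genes without the leading word held another word that passed for a fall, which is given beside them below as another associated word. Such words are common. Between 31.6% (E2F3) and 60.2% (TGIF2) of the loci not called held the leading or another associated word. Among falls the share ran from 68.3% (THAP5) to 95% (TERF1). Another associated word thus says little about a single gene, and lists without such UTRs have fewer members to test.

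**Figure D3:**
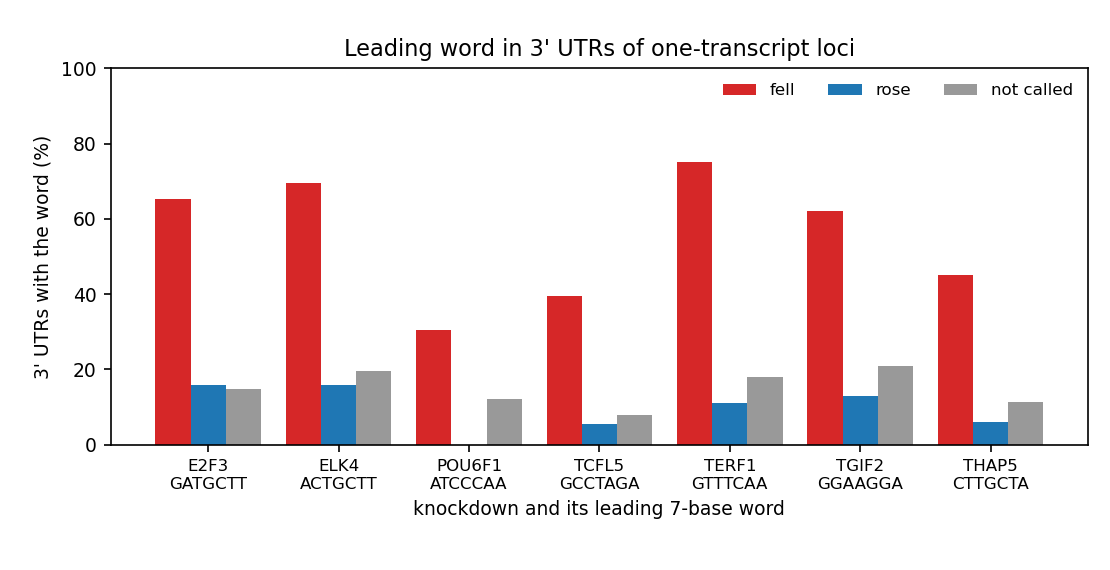
Share of 3' UTRs (y axis, percent) that hold the leading word of each knockdown (x axis, with the word), among one-transcript loci that fell (red), rose (blue) or were not called (grey). The share among falls runs from 30.4% for POU6F1 to 75% for TERF1, and among genes not called from 7.76% to 20.9%.

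The E2F3 comparison asked which genes depend on E2F3, a member of the E2F family of S-phase regulators. Genes of DNA replication and the G1/S transition rose: 6 of 25 measured members were called higher, 10 when adjusted over the list alone, none was called lower, and the list median was 0.61 (limma cameraPR, Benjamini-Hochberg adjusted p = 7.39e-12). Among them in the authors' deposited table were E2F1, which drives S-phase entry (0.84, SE 0.18, adjusted p = 0.000333), MCM6, a subunit of the replicative helicase (0.66, SE 0.14), and CDC6, which loads that helicase (0.93, SE 0.24). Replication-dependent histone genes were shifted upward as a list, with a median of 0.23 and 10 of 10 values above 0, though no member was called singly, over all genes or adjusted over the list alone (cameraPR adjusted p = 0.0063). The mitosis list did not pass (0 of 23 called, also adjusted over the list alone, cameraPR adjusted p = 0.955), with a median of -0.00, a mean of 0.03 and a negative test.

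Outside these lists and apart from FUT8, HMGA2, a chromatin architectural protein, led the rises in the authors' deposited table for E2F3 (1.13, SE 0.18). This ranking covers one-transcript loci with a mean of at least 100. CDK6, a G1 kinase (1.07, SE 0.17), and HELLS, a chromatin remodeller (1.06, SE 0.21), followed in the authors' deposited table. FUT8 was listed near 0 in the control arm, with a fitted value of 9.33 in the authors' deposited table. TGFBR1, a TGF-beta receptor (-1.46, SE 0.33), ACTR8 (-1.18), UBL5 (-1.14), GSKIP (-1.11) and IGF2R, the receptor that clears IGF2 (-1.11, SE 0.30), fell in the authors' deposited table, and all of these 5 held the word GATGCTT. So did CDK6, CDC6, MCM6 and FUT8, which rose. TCEA1 (-1.01) and ACTA2, smooth muscle actin (-0.58, SE 0.14), fell without it or another associated word in the authors' deposited table for E2F3. Cell surface markers of stromal cells MME (0.73) and NT5E (0.68, with a locus log2 ratio of 0.50) rose there. The identity list itself did not pass (2 of 16 rose, 3 adjusted over the list alone, median 0.01, cameraPR adjusted p = 0.0573). NF-kB and cytokine genes had a median of 0.52 with 0 of 9 called and 2 adjusted over the list alone, BIRC3 and CXCL8 (cameraPR adjusted p = 0.0236). With a preset correlation of 0.05 between genes the adjusted p of that list was 0.0779, and with a minimum mean of 100 it was 0.710.

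ELK4 is a ternary complex factor of the ETS family, which acts with SRF at promoters of immediate-early genes. Its knockdown lowered the G1/S list as a group: 19 of 23 values were below 0, with a median of -0.55, and PCNA, the sliding clamp of DNA polymerase, was the single member called (-0.69, SE 0.17, adjusted p = 0.0053 in the authors' deposited table). Adjusted over the list alone, 2 fell (cameraPR adjusted p = 7.00e-06). The list thus moved in opposite directions in E2F3 and ELK4, which share all 3 control libraries, while the mitosis list did not pass for ELK4 (median -0.17, 0 of 22 called, 0 adjusted over the list alone, cameraPR adjusted p = 0.789). The difference between the knockdowns was not tested.

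SKP2, which marks cell-cycle inhibitors for degradation (-0.80, SE 0.12), and ELK3, a second ternary complex factor (-1.08, SE 0.21, adjusted p = 4.41e-05), fell in the authors' deposited table for ELK4. So did ELOVL5, a fatty acid elongase (-1.34, SE 0.22), EDEM3 (-1.29), CNOT6, a deadenylase subunit (-0.97), and KIAA1191 (-0.89), per the authors' deposited table. These 6 and PCNA all held the word ACTGCTT. Rises in the authors' deposited table included CNNM2 (1.63, SE 0.22), which also held it, the growth factor HGF (1.03, SE 0.24), RPL12 (1.07), STX17 (0.74), the protease PAPPA (0.72) and the cholesterol exporter ABCA1 (0.64).

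Smaller upward shifts in the ELK4 table involved 4 lists. The TGF-beta response list had 1 of 19 called, COL4A1 (0.41, SE 0.08 in the authors' deposited table), 1 adjusted over the list alone and a median of 0.22 (cameraPR adjusted p = 0.0096). The extracellular matrix list had 1 of 23 called, the collagen COL3A1 (0.38, SE 0.09 in the authors' deposited table, with the word ACTGCTT), and 4 adjusted over the list alone, of which 3 rose. Its median of 0.17 and its test were positive (cameraPR adjusted p = 0.0356), and its mean of -0.03 was not. Stromal identity had 1 of 16 called, NT5E (0.41 in the authors' deposited table), 5 adjusted over the list alone, of which 4 rose, and a median of 0.09 (adjusted p = 0.0176). NT5E held 75.3% of its locus, whose sum had a log2 ratio of 0.32. In one-transcript loci the identity list had a cameraPR adjusted p of 0.251. Immediate-early genes had 1 of 16 called, JUN (0.59, SE 0.17 in the authors' deposited table), 1 adjusted over the list alone and a median of 0.30 (cameraPR adjusted p = 0.0421). With a preset correlation of 0.05 the adjusted p-values of these 4 lists were 0.0744, 0.185, 0.0909 and 0.168 in that order, and none of the 4 passed among genes without an associated word in the 3' UTR.

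POU6F1 encodes a POU-homeodomain factor. In the authors' deposited table for its knockdown, NOTCH3, a receptor found on mural cells (-1.16, SE 0.23, adjusted p = 0.000127), and CSPG4, the proteoglycan NG2 (-0.36, SE 0.10), fell. These were the 2 members called, also adjusted over the list alone, among 7 measured markers of smooth muscle cells and pericytes (median -0.11, cameraPR adjusted p = 0.01). Extracellular matrix genes shifted downward, with 18 of 23 values below 0 and a median of -0.15, though none was called and 1, MMP1, passed adjusted over the list alone (cameraPR adjusted p = 0.0197). The mitosis list shifted upward with a median of 0.19: CDK1, the mitotic kinase, rose (0.52, SE 0.13 in the authors' deposited table), and 2 of 22 passed adjusted over the list alone (cameraPR adjusted p = 0.0197). With a preset correlation of 0.05 the adjusted p was 0.133 for both the matrix and the mitosis list. The marker and matrix lists did not pass among genes without an associated word in the 3' UTR.

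DEPDC1, GPSM2, which orients the spindle, and HMGB3 rose by 0.86, 0.93 and 0.71 in the authors' deposited table for POU6F1, as did PGM2L1 (0.94, SE 0.21), FBXO25 (0.75) and ARRDC3 (0.59). KDELR2, a receptor that returns proteins to the endoplasmic reticulum (-1.36, SE 0.23), the metalloreductase STEAP3 (-1.31, SE 0.25), PMP22, a myelin protein (-1.08, SE 0.16), and VBP1, a prefoldin subunit (-0.91, SE 0.16), fell in the authors' deposited table. STEAP3 and PMP22 held the word ATCCCAA, NOTCH3 and KDELR2 held another associated word, and CSPG4 and VBP1 held none. The G1/S list did not pass (median 0.18, 0 of 24 called, 0 adjusted over the list alone, cameraPR adjusted p = 0.0649).

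TCFL5 is a basic helix-loop-helix factor. After its knockdown the cell-cycle lists were low: all 23 mitosis genes had negative values with a median of -1.34, and 4 fell, or 12 adjusted over the list alone (cameraPR adjusted p = 1.12e-11). In the authors' deposited table these included MKI67, the proliferation antigen Ki-67 (-1.34, SE 0.31), and UBE2C, which acts in mitotic exit (-1.34, SE 0.38). The G1/S list had a median of -1.12, with 4 of 22 members lower, or 10 adjusted over the list alone (cameraPR adjusted p = 2.61e-11). MCM2, a helicase subunit (-1.61, SE 0.27), and CLSPN, a checkpoint mediator (-1.80, SE 0.39), were among them in the authors' deposited table. Histone genes had a median of -0.94, and none of 9 was called, but 6 fell adjusted over the list alone (cameraPR adjusted p = 3.00e-06). The 7SL RNA, a component of the signal recognition particle, took 26.3% of normalised counts in the knockdown arm and 22.2% in the control arm of this table.

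Targets of p53 rose with TCFL5 knockdown: 5 of 22 were called higher, 8 adjusted over the list alone, with a median of 0.45 (cameraPR adjusted p = 3.76e-07). The authors' deposited table gave FDXR, a mitochondrial reductase, at 1.65 (SE 0.27, adjusted p = 1.64e-07), BTG2, an antiproliferative gene, at 1.68 (SE 0.30) and the stress gene SESN1 at 1.61 (SE 0.35). HMOX1, which degrades heme (2.01, SE 0.36), TXNIP, an inhibitor of thioredoxin (1.10, SE 0.10), ARRDC4 (1.28) and KIAA0319L (1.3) also rose in the authors' deposited table. Targets of SRF and MRTF in the cytoskeleton were lower, with 2 of 17 called, also adjusted over the list alone, and a median of -0.47 (cameraPR adjusted p = 0.000477). They were CCN2 (-0.76, SE 0.17) and ACTG1, a cytoplasmic actin (-0.52, SE 0.14), and SRF itself fell (-1.14, SE 0.23) in the authors' deposited table for TCFL5.

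Matrix genes went both ways after TCFL5 knockdown, with FN1, fibronectin (-1.37, SE 0.29), and TIMP3 (-0.86, SE 0.11) lower and COL3A1 (0.53) and SPARC (0.56) higher in the authors' deposited table. The list as a whole did not pass (2 of 23 rose, 2 fell, 4 adjusted over the list alone, median 0.08, cameraPR adjusted p = 0.819). SERPINE1, a TGF-beta response gene (-1.04, SE 0.18), and HAS2, a hyaluronan synthase (-1.60, SE 0.32), fell, and LTBP1 (0.73) rose, in the authors' deposited table. HOXA11, required for endometrial development, rose (0.56, SE 0.13) and the Wnt inhibitor DKK1 fell (-0.46, SE 0.11) in the authors' deposited table for TCFL5. Among one-transcript loci with a mean of at least 100, TMX3 (-2.38, SE 0.47) and TGM2, a transglutaminase (-2.14, SE 0.44), fell most in the authors' deposited table for TCFL5. ARHGDIB (-1.90), TMEM47 (-1.73) and WWC2 (-1.71) followed in the authors' deposited table, and all 5 held the word GCCTAGA. MKI67, SRF, HAS2 and DKK1 held another associated word, and CCN2, SERPINE1 and TIMP3 held none. Lysosome and autophagy genes passed upward (0 of 18 called, 2 adjusted over the list alone, median 0.20, cameraPR adjusted p = 0.0200), with an adjusted p of 0.116 at a preset correlation of 0.05 and of 0.402 in one-transcript loci.

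TERF1 is a shelterin protein that binds telomeric repeats. Its knockdown had the fewest one-transcript calls. Genes of cholesterol biosynthesis were shifted downward together: all 20 values were negative, with a median of -0.28, although none was called singly or adjusted over the list alone (cameraPR adjusted p = 0.000338). Examples chosen after their values were seen were, in the authors' deposited table, MVD (-0.45, SE 0.16) and HMGCR, the rate-limiting enzyme of the pathway (-0.28, SE 0.23). Targets of p53 shifted upward with a median of 0.20 and 17 of 21 values above 0, with 0 called and 1, SESN2, adjusted over the list alone (cameraPR adjusted p = 0.0057). With a preset correlation of 0.05 the adjusted p of the p53 list was 0.0575.

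MET, the receptor for HGF, fell by 1.3 on the log2 scale (SE 0.21, adjusted p = 3.17e-07), as did NEK7, a mitotic kinase (-1.09, SE 0.27), neither with the word GTTTCAA, in the authors' deposited table for TERF1, though NEK7 held another associated word. CMTM3 (-1.10), SPOPL (-1.10), ANKMY2 (-1.04) and the cargo receptor LMAN2 (-1.03) fell in the authors' deposited table and held it. ITGA3, an integrin subunit (0.72, SE 0.13), TNFRSF10D, a decoy receptor for TRAIL (0.63, SE 0.11), the cadherin CDH6 (0.80, with the word GTTTCAA), TDG (0.66), CCDC85B (0.77) and ADAMTS2 (0.51) rose in the authors' deposited table. The telomere list passed downward (1 of 20 fell, 1 adjusted over the list alone, median -0.18, cameraPR adjusted p = 0.0373), but its called member was TERF1 itself. The adjusted p was 0.177 at a preset correlation of 0.05, and with a minimum mean of 100 the difference of mean Wald statistics turned to 0.13. The hypoxia list passed upward (1 of 16, 1 adjusted over the list alone, median 0.07, cameraPR adjusted p = 0.0036) because of a P4HA2 transcript listed at 10.79 whose locus had a ratio of -0.30. Restricted to one-transcript loci, that list had an adjusted p of 0.548. Neither cell-cycle list passed with TERF1 knockdown (G1/S median 0.04, 0 of 24 called; mitosis median 0.01, 0 of 23 called; 0 adjusted over the list alone in both; cameraPR adjusted p = 0.955 for each), and the test had the opposite sign to the median and mean in both.

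TGIF2 is a homeodomain corepressor of TGF-beta signalling, and its knockdown had the most calls. Cytokine and NF-kB genes rose: all 10 measured values were positive, with a median of 1.18, and 3 were called, or 5 adjusted over the list alone (cameraPR adjusted p = 2.04e-05). In the authors' deposited table they included BIRC3, an inhibitor of apoptosis (1.63, SE 0.36), and SOD2, the mitochondrial superoxide dismutase (0.83, SE 0.22). With a minimum mean of 100 the adjusted p of the cytokine list was 0.189. Extracellular matrix genes rose, with 3 of 23 called, 4 adjusted over the list alone and a median of 0.31 (cameraPR adjusted p = 0.000146), among them LOXL1, a collagen and elastin crosslinker (0.76, SE 0.14), and SPARC (0.51, SE 0.10) in the authors' deposited table. The decidualization list also shifted upward (median 0.44, cameraPR adjusted p = 0.0051): IL11, a cytokine needed for decidualization, was the single member of 14 called (1.76, SE 0.34, adjusted p = 2.42e-05 in the authors' deposited table), and 2 passed adjusted over the list alone. The lowest adjusted p of that list in another table was 0.086, for ELK4.

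Cell-cycle lists were lower after TGIF2 knockdown. Of 23 G1/S genes 6 fell, or 8 adjusted over the list alone, with a median of -0.55 (cameraPR adjusted p = 7.00e-06), among them DHFR, which supplies folate for nucleotide synthesis (-1.35, SE 0.24), and E2F1 (-1.74, SE 0.36) in the authors' deposited table. Of 23 mitosis genes 1 fell, KIF20A (-0.94, SE 0.17 in the authors' deposited table), or 6 adjusted over the list alone, with a median of -0.70 (cameraPR adjusted p = 2.32e-05). The 7SL RNA took 26.8% of normalised counts in the knockdown arm against 18.6% in the control arm. Immediate-early genes shifted upward (3 of 16 rose, 3 adjusted over the list alone, median 0.41, cameraPR adjusted p = 0.0124), with JUNB (0.88, SE 0.22) and BTG2 (0.94, SE 0.27) in the authors' deposited table, and so did stromal identity genes (2 of 16 rose, 2 adjusted over the list alone, median 0.27, adjusted p = 0.0069). With a preset correlation of 0.05 these 2 lists had adjusted p-values of 0.0756 and 0.0537, and the identity list had 0.652 among genes without an associated word in the 3' UTR.

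Apart from PDIA4, IGF2BP3, a fetal RNA-binding protein (2.54, SE 0.40), and TFPI2, a protease inhibitor (2.37, SE 0.31), led the rises in the authors' deposited table for TGIF2. This ranking covers one-transcript loci with a mean of at least 100. KITLG, the ligand of KIT (1.83, SE 0.32), the endopeptidase MME (1.83, SE 0.52) and the guidance cue SLIT2 (1.76, SE 0.42) followed in the authors' deposited table. HSPA5, the chaperone BiP, rose by 0.66 on the log2 scale (SE 0.10), and PDIA4, listed near 0 in the control arm, had a fitted value of 6.19 in the authors' deposited table. PDIA4 was also called for THAP5 (5.53 in the authors' deposited table), which has the same 3 control libraries, so its value is not particular to TGIF2. SERPINE1 (-1.25, SE 0.17), CCN2 (-0.79, SE 0.20) and LMOD1 (-0.88, SE 0.20) fell in the authors' deposited table for TGIF2, while the TGF-beta list did not pass (1 of 18 rose, 1 fell, 2 adjusted over the list alone, median 0.12, cameraPR adjusted p = 0.963). Further falls were MINDY2 (-2.07, SE 0.41), the syntaxin STX2 (-1.95, SE 0.15), TOR1A (-1.71), RASSF3 (-1.67), GXYLT1 (-1.66) and GNG11 (-1.64) in the authors' deposited table. These 6 and LMOD1 held the word GGAAGGA, as did SOD2, which rose, while SERPINE1 and CCN2 held another associated word, and KIF20A held none.

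THAP5 is a zinc-finger protein of the THAP family. Its knockdown lowered mitosis genes: all 23 values were negative with a median of -1.18, and 9 fell, or 13 adjusted over the list alone (cameraPR adjusted p = 3.42e-18). They included KIF11, a spindle motor (-1.26, SE 0.24, adjusted p = 4.68e-05), and BUB1, a checkpoint kinase (-1.50, SE 0.32), in the authors' deposited table. Of 23 G1/S genes 5 fell, or 10 adjusted over the list alone, with a median of -0.97 (cameraPR adjusted p = 1.51e-13), among them GINS1, a helicase subunit (-1.66, SE 0.32), and DHFR (-1.12, SE 0.25) in the authors' deposited table. The kinetochore protein KNL1 fell as well (-1.33, SE 0.29 in the authors' deposited table). Targets of p53 shifted upward with a median of 0.35, 0 of 21 called and 2 adjusted over the list alone (cameraPR adjusted p = 0.0036). The 7SL RNA took 23.5% of normalised counts in the knockdown arm and 18.6% in the control arm.

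SCD, the stearoyl-CoA desaturase (-1.33, SE 0.28), the glutathione reductase GSR (-1.34, SE 0.26), DOCK5 (-1.58, SE 0.43) and SERINC5 (-1.45, SE 0.32) fell in the authors' deposited table for THAP5. COX7A2, a subunit of cytochrome oxidase (2.15, SE 0.58), GTF2A2, a basal transcription factor (1.3, SE 0.25), TXNIP (1.19, SE 0.27), the Wnt receptor FZD6 (0.77) and VAT1L (0.72) rose in the authors' deposited table. GSR, DOCK5, SERINC5 and KIF11 held the word CTTGCTA, SCD held another associated word, and KNL1 and BUB1 held none. Mitochondrially encoded genes shifted downward (12 of 12 negative, median -0.63, 0 called, 1 adjusted over the list alone, cameraPR adjusted p = 0.0114), and ribosomal protein genes upward (23 of 26 positive, median 0.30, 0 called, 0 adjusted over the list alone, cameraPR adjusted p = 0.0216). At a preset correlation of 0.05 their adjusted p-values were 0.0574 and 0.162.

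**Figure D4:**
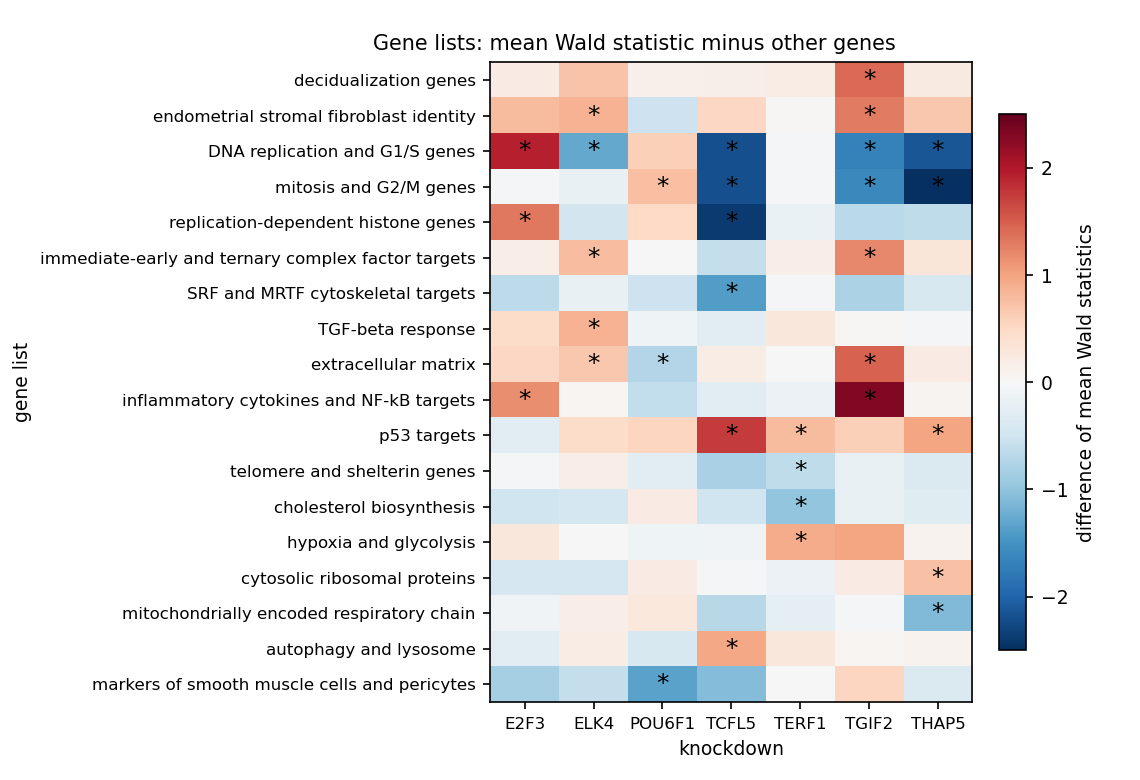
Difference between the mean Wald statistic of each gene list and that of the other genes (colour) for the lists called in at least 1 of the 7 knockdowns (x axis), with asterisks at cameraPR adjusted p under 0.05. The G1/S list is higher for E2F3 (1.95) and lower for ELK4 (-1.29), TCFL5 (-2.20), TGIF2 (-1.69) and THAP5 (-2.14).

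**Figure D5:**
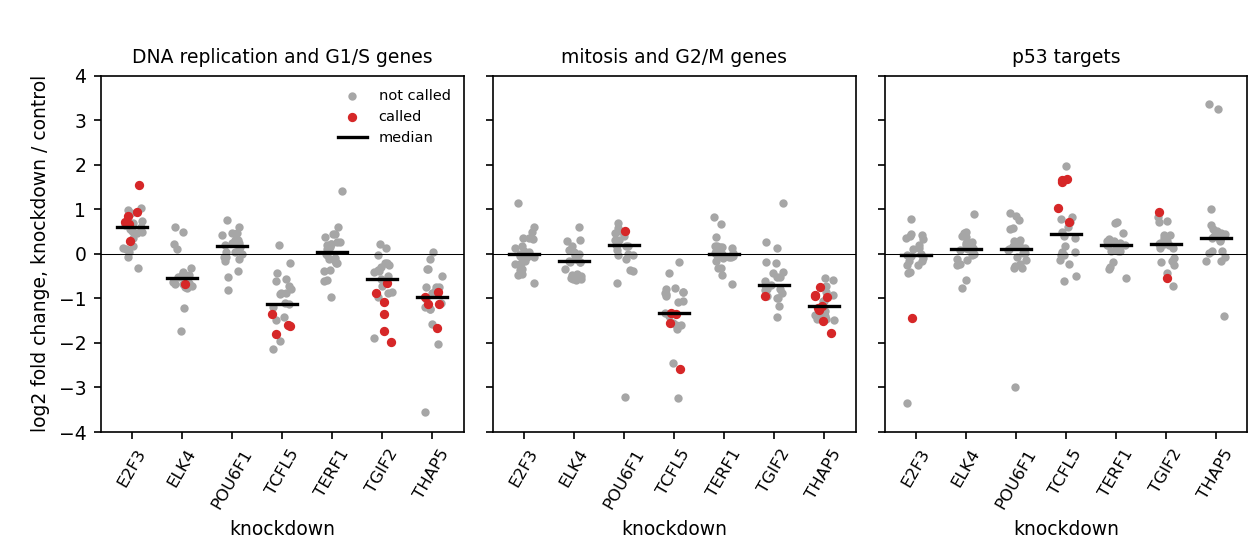
Log2 fold changes (y axis) of the members of 3 gene lists in each knockdown (x axis), with called members in red, the others in grey and the list median as a bar. The mitosis medians are -1.34 for TCFL5, -0.70 for TGIF2 and -1.18 for THAP5, against 0.01 for TERF1.

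Across the 7 tables, 33 of 147 list tests passed, and 19 passed with a preset correlation of 0.05. An estimated correlation could not be had without values of single libraries. Interferon-stimulated genes, a common response to foreign RNA, passed in no table: 11 of 27 were measured, none was called or passed adjusted over the list alone, and medians ran from 0.01 to 0.23 (lowest cameraPR adjusted p = 0.322). For THAP5 the mean and the test of that list were negative and its median positive. The controls received an oligonucleotide too, so an interferon response common to both arms would not show in these fold changes. The amino acid and unfolded protein list passed in no table either (lowest cameraPR adjusted p = 0.247, for TGIF2), and its median and mean differed in sign for E2F3, TCFL5 and TERF1. For TGIF2, 2 of 19 members rose, and the median was 0.08. Adjusted over the list alone 4 were called, of which 2 rose and 2 fell. Epithelial markers, of which between 3 and 5 of 14 were measured, passed in no table (lowest cameraPR adjusted p = 0.352), and their median and mean differed in sign for E2F3, TERF1 and TGIF2. Endothelial markers had 2 of 10 measured and immune markers 0 of 12, so neither was tested.

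Relatives of the targets were looked up after the values were seen, and 4 of the 26 measured were called, or 5 adjusted over these relatives alone. E2F1 rose with E2F3 knockdown and ELK3 fell with ELK4 knockdown, as given above, while ELK1, the other ternary complex factor, stood at 0.02 (adjusted p = 1) in the authors' deposited table. POU2F2, a POU factor of lymphocytes, fell with POU6F1 knockdown (-1.3, SE 0.28 in the authors' deposited table). A TGIF1 transcript rose with TGIF2 knockdown (5.11 in the authors' deposited table). It held 1.9% of its locus in the control arm, and the locus sum had a log2 ratio of 0.87. Another TGIF1 transcript rose for both TGIF2 (2.21) and THAP5 (2.31) in the authors' deposited tables, and these knockdowns share their 3 control libraries. Whether a rise of TGIF1 is particular to TGIF2 knockdown was not tested.

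Fold changes of knockdowns that share control libraries are correlated without any effect. Over 21 pairs, r across transcripts (which are not independent replicates) was set beside its value in 100 simulations of unchanged groups against the shared controls. E2F3 and ELK4, with 3 shared libraries, had r = 0.553 against a simulated 0.452 and a covariance of 0.277 against 0.207, but in one-transcript loci r was 0.432 against 0.462 and the covariance 0.0285 against 0.0351. TCFL5 and THAP5, with 2 shared libraries, had r = 0.353 against 0.296 over all loci and 0.392 against 0.304 in one-transcript loci, with a covariance of 0.0491 against 0.0363. They shared 10 falls there, where independent lists give 1.43 and the simulation 7.16. The 3 pairs among TERF1, TGIF2 and THAP5 share 3 libraries and lay below every simulated value in one-transcript loci. There r was 0.212 against a simulated mean of 0.475 (lowest 0.427) for TERF1 and TGIF2. It was 0.261 against 0.476 (lowest 0.400) for TERF1 and THAP5, and 0.327 against 0.484 (lowest 0.435) for TGIF2 and THAP5. Over all loci these were 0.434 against 0.461, 0.351 against 0.456, and 0.461 against 0.458. TGIF2 and THAP5 shared 9 falls in one-transcript loci, where independent lists give 1.74 and the simulation 14.1. The simulation treats every call as chance shared through the controls, and it gave higher r than these pairs had there. It is thus no measure of whether their overlap is low. ELK4 and TCFL5 share no control library. Their r was -0.0033 over all loci against a simulated -0.0018, and -0.0712 in a subset with higher means. In one-transcript loci it was 0.207, against a highest simulated value of 0.0759. Other pairs without a shared library left the simulated range there too, such as POU6F1 with TERF1 (0.146, highest 0.0651) and E2F3 with THAP5 (-0.0985, lowest -0.0722). E2F3 with TCFL5 (0.0596, highest 0.142) stayed within it. The simulation drew each transcript independently, so its range may be too narrow. Passing it does not by itself show a relation between knockdowns. The controls could not be split without values of single libraries, so part of any excess in pairs with shared libraries may come from those controls. Pairs without a shared library cannot owe an excess to shared controls, and the cause of theirs was not tested.

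In one-transcript loci, 103 transcripts were called in the same direction in at least 2 tables. Independent lists give 20.6, and the simulation with shared controls 79.9 on average and 99 at most. That simulation treats every call as chance and missed the r of the pairs among TERF1, TGIF2 and THAP5, so these counts are a description. Over all loci the count was 194, against 36.8 and 157.5. TGM2 was lower in 4 of the authors' deposited tables, at -0.46 for E2F3, -0.73 for ELK4, -2.14 for TCFL5 and -1.11 for THAP5, and higher for TGIF2 at 0.86; its 3' UTR held the leading words of TCFL5 and TGIF2 and another associated word of E2F3 and ELK4. IGF2BP3 rose with TCFL5 (2.06), TERF1 (1.71) and TGIF2 (2.54), and HMGA2 with E2F3 (1.13), TCFL5 (0.82) and TGIF2 (1.47), in the authors' deposited tables. The same tables, TCFL5, TGIF2 and THAP5, shared falls of the nuclear lamin LMNB1 (-1.12, -0.73 and -1.08), of RACGAP1, which acts in cytokinesis (-1.01, -0.72 and -1.19), and of HJURP, a centromere chaperone (-1.18, -1.31 and -0.99) in the authors' deposited tables. They also shared rises of TXNIP (1.10, 0.95 and 1.19), per the authors' deposited tables. TCFL5, TERF1, TGIF2 and THAP5 have control libraries of Ctrl6 in common, so values that recur among them are not independent.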

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

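The one-transcript settings, the lists without the targeted gene and the settings without UTRs that hold an associated word were added after the data were seen; all others had been fixed before. No paired analysis was possible because the deposited tables hold no values of single libraries and reads were not realigned, so a replicate block, leave-one-out fits, TMM normalisation and a swap of the testing tool were not run. After the median fold change was subtracted, all 7 targets kept their direction and their side of the threshold. They also kept their side with standard errors multiplied by the square root of 2. Larger standard errors cannot change a direction, nor could they have made POU6F1, which was not called, pass. That multiplication stands for 2 runs counted as separate libraries, although the 6 single-read values per table were those of 3 libraries per arm. It left 82 calls for E2F3, 84 for ELK4, 71 for POU6F1, 118 for TCFL5, 74 for TERF1, 224 for TGIF2 and 89 for THAP5. One-transcript calls were 19, 10, 5, 55, 8, 116 and 16 in the same order. Without UTRs that hold an associated word, 70, 32, 26, 124, 15, 123 and 71 one-transcript calls were left. Those falls in number follow from the construction of the alternatives. An adjusted p under 0.01 gave 179 for E2F3 and 270 for TCFL5, and a log2 change of at least 1 gave 183 for E2F3, 287 for TCFL5 and 429 for TGIF2. An empirical null, with a robust spread of the Wald statistics of between 0.753 and 0.986, raised the calls to 399 for ELK4, 393 for POU6F1 and 435 for TERF1.

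Of the 33 list calls, 19 were left at a preset correlation of 0.05 and 16 under every alternative. Of the list results followed, one-transcript loci left 34 on their side of the threshold, weakened 5 and strengthened 3, ranks left 34, a minimum mean of 100 left 34 and no minimum left 37. Without UTRs that hold an associated word 29 stayed, and without the targeted gene 41. Of the correlations, 5 stayed within 1 simulated standard deviation as Spearman correlation, 7 at higher means and 2 in one-transcript loci. The telomere list in TERF1 reversed to a difference of 0.13 with a minimum mean of 100 (cameraPR adjusted p = 0.855), and the cause was not tested. The correlation of E2F3 with TCFL5, -0.0719, reversed to 0.0336 as Spearman correlation and was 0.0982 at higher means and 0.0596 in one-transcript loci, while that of POU6F1 with TCFL5 went from 0.173 to -0.128 at higher means; the cause was not tested. The count of transcripts called in the same direction in at least 2 tables went from 194 to 35 with the larger standard errors, against 25.1 in the simulation and 37 at its highest, and to 103 in one-transcript loci. Depth limits transcripts with low means, such as POU6F1 itself.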

Other observations

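MET, the HGF receptor, was lower in the authors' deposited table for TERF1 and higher in that for TGIF2 (0.82, SE 0.22, adjusted p = 0.0093). TNFRSF10D, the decoy receptor, rose in the authors' deposited tables for TCFL5 (0.52, SE 0.15), TERF1 (0.63, SE 0.11) and TGIF2 (0.95, SE 0.10). These knockdowns have control libraries of Ctrl6 in common, so the TNFRSF10D values are not independent. CEP55, which acts in the last step of cell division, fell in the authors' deposited tables for ELK4 (-0.73, SE 0.14), TGIF2 (-0.58, SE 0.18) and THAP5 (-1.25, SE 0.29). MLEC, a carbohydrate-binding protein of the endoplasmic reticulum, fell for E2F3 (-0.39), TCFL5 (-1.38) and TGIF2 (-0.92) in the authors' deposited tables, and its 3' UTR held the leading word of each of these 3 knockdowns. VBP1 fell for ELK4 (-0.58) and TERF1 (-0.58), whose words it holds, and for POU6F1 (-0.91), whose word it does not hold, in the authors' deposited tables. SCD fell for TCFL5 (-1.18, SE 0.33) as well as for THAP5 in the authors' deposited tables.

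Tests of the shared-locus pattern by locus sums, of control libraries and of 7SL scaling were chosen after the results had been seen; those of isoform choice and of seed matches were written before their own values were computed. Some transcripts of the same locus moved in opposite directions by large amounts. Of 796 pairs of a shared locus and a table with a called change of over 8-fold, 94 had such calls in both directions, and of the 141 transcripts with such calls in at least 2 tables, 21 went in opposite directions between tables. The locus sum stayed within 1.5-fold for 79.5% of calls in shared loci, so reads of a locus assigned to another of its transcripts may account for most of these calls. A change of isoform choice by the siRNA was set against this. Between the Ctrl5 and Ctrl6 controls, which had no targeting siRNA, 444 transcripts differed at least 8-fold at a steady locus. The median between control and knockdown arms was 388. Switches of this size thus also arose without a targeting siRNA, which that explanation did not predict. Both counts took in transcripts that were not called, whereas large calls in shared loci numbered between 110 and 163 per table. The counts therefore cannot decide the question for the called transcripts. Single loci with a real switch cannot be told apart from the others in these tables.

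Genes beyond the target that fell often held a word in the 3' UTR that also lies in the targeted transcript. This held in 7 of 7 tables, where 1.31 would be expected by chance (p = 4.26e-06, exact product of the shares of words found in each target), as seed matches of the siRNA in 3' UTRs predict. Microarray and sequencing studies have long described such microRNA-like effects of siRNA, and they are a candidate explanation for genes with the word, such as TGFBR1, ELK3, SKP2, PCNA, TGM2, STX2 and KIF11. Genes without any associated word, such as MET in TERF1, CSPG4 in POU6F1, SERPINE1 in TCFL5 and BUB1 in THAP5, could still respond to the target or to other genes hit by the siRNA. The series holds a single siRNA treatment per target as labelled, so no biological explanation was tested.

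Cell-cycle genes were low in TCFL5, TGIF2 and THAP5, which use control libraries of Ctrl6 wholly or in part. High levels in those controls are unlikely, since TERF1, with the same 3 libraries as TGIF2 and THAP5, had a G1/S median of 0.044. A single scaling factor from the abundant 7SL RNA would move every transcript alike. The list medians lay below those of other transcripts in the same range of means. The smallest log2 gap was -0.55, in the G1/S list of TGIF2 (SE of the list mean 0.13). These lists had already passed a test against other genes, so the gap speaks only to a single factor. The log2 ratio of 7SL RNA between arms was 0.32 for TCFL5, 0.74 for TGIF2, 0.63 for THAP5 and 0.06 for TERF1. It was -0.27 for ELK4, where the G1/S list also fell. Other effects that go with the 7SL share were not tested. A knockdown library of low depth was present in each of these comparisons, with a size factor of 0.831 for TCFL5, 0.815 for TGIF2 and 0.820 for THAP5. The lowest size factor was 0.912 for TERF1 and 0.973 for ELK4, where the G1/S list also fell. Whether the falls rest on those libraries could not be asked without values of single libraries. Seed matches in the list members themselves do not account for the whole of the falls, since members without an associated word kept at least 73% of the list median, though in that G1/S list of TGIF2 the 12 members with a word had a median of -0.87 against -0.41 for the others. An indirect effect through another gene hit by the siRNA, or slower growth after transfection, may still lie behind them, and neither was tested.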
